A study of Mus musculus with 8 samples.

How the data were processed

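RNA sequencing was done on tibialis anterior, a muscle of the lower leg, from mice aged 12 to 14 weeks. The labels define 4 groups of 2 libraries each: healthy Balb/c mice, Balb/c mice with cachexia (wasting of muscle in cancer) from the metastatic breast cancer line 4T1, healthy CD2F1 mice, and CD2F1 mice with cachexia from the metastatic colon cancer line C26m2. Per the labels' protocols, tumours were cut out 2 to 3 weeks after injection of the cancer cells and the mice were killed 5 weeks after injection, when metastases had been seen by imaging. Libraries came from poly-A RNA prepared with the Illumina TruSeq RNA kit, per the labels' protocols, and strand use is not given in the sources used here. Nothing in the labels says which library came from which animal, so the p-values cannot be read as measuring the spread between animals.

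The submitters' processing notes name TopHat2 2.1.0, Cufflinks 2.2.1 and Cuffdiff, with the mouse build NCBIM37. The annotation release and the library normalization are not given in the sources used here. Each of the 2 tables lists significant genes of 1 comparison, tumour-bearing against healthy muscle of the same strain. The authors' group values are in FPKM (fragments per kilobase of transcript, scaled to the number of fragments), per the file headers, with 1 value per group. The deposited log2 fold change is, per the file headers, that of the tumour-bearing over the healthy group. Its largest distance from the log2 ratio of the listed FPKM values was 1.4e-05, so no pseudocount had been added. The p-value and q-value columns are the authors' Cuffdiff results, per the file headers and the labels. All p-values are multiples of 5e-05, which is also the smallest, and 1727 genes of the 4T1 table and 2058 of the C26m2 table sit at it. No listed gene had a group value of 0.

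Per-library values were not used here, so no value below carries an SD, and sequencing depth is unknown. Genes outside a table are neither called unchanged nor counted. Under Benjamini-Hochberg adjustment, q times rank over p gives the number of genes tested. That product ran from 13178 to 13337 in the 4T1 table (median 13218) and from 13117 to 13147 in the C26m2 table (median 13121). It was not constant, so the number tested is approximate.

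A gene counts as called when its table lists it, at q of 0.05 or less. Folds are the ratio of the authors' 2 group FPKM values. The tables gave no test statistic, which the planned test of a difference between models needed. Its standard error was taken instead as the absolute log2 fold change divided by the normal quantile that the deposited p-value implies. At the smallest p-value this is an upper bound, equal to 24.7% of the log2 fold change. Differences were tested by a normal approximation with Benjamini-Hochberg adjustment over genes listed in both tables, matched by symbol. On simulated data made from the 4T1 comparison (13000 genes, 200 moved by 4 on the log2 scale), this test found 100% of moved genes whose signs became opposite and 0% of those whose signs stayed equal. On data made in the same way from the C26m2 comparison it found 100% and 15.9%. It therefore misses most differences between changes of equal sign, and for genes called in opposite directions it restates the signs.

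Before the data were examined, 33 lists were fixed. Of these, 23 are gene groups: atrophy ubiquitin ligases, proteasome, autophagy and lysosome, FoxO and glucocorticoid targets, metallothionein with zinc and iron genes, IL-6 and STAT3 with acute phase, NF-kB and TNF response, TGF-beta with activin and BMP, extracellular matrix, fast and slow fibre contraction, oxidative phosphorylation, TCA cycle with mitochondrial biogenesis, glycolysis, fatty acid metabolism, denervation, satellite cells and myogenesis, ATF4 and endoplasmic reticulum stress, IGF and mTOR, circadian clock, interferon and MHC, oxidative stress with heat shock, and proliferation. The other 10 are markers of macrophages, neutrophils, red cells, lymphocytes, adipocytes, endothelium, fibroblasts, Schwann cells, tendon and epithelium. Within each table the higher and lower members of a list were set against the higher and lower other genes by Fisher's exact test, two-sided. Adjustment was over 64 tests, those of the 32 lists with 3 or more listed members in either table. The tables hold called genes, so this tests direction, not enrichment, and a count adjusted over a list alone was not computed. On simulated data with independent genes, 5.5% of random lists passed p of 0.05 for the 4T1 comparison and 2.5% for the C26m2 comparison. Genes of a real list can move together, which the simulation did not cover. The p-values of lists and gene families treat genes as independent and may be too small. List symbols were matched through the tables' own symbols, Ensembl identifiers and the synonyms of the reference gene table (assembly GRCm38.p6), whose build differs from the authors', so no coordinates are given. Of 4334 and 4832 identifiers, 4265 and 4759 were in that reference.

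The genes named were chosen by a rule fixed before the data were examined: per comparison, among genes with 1 FPKM or more in a group, the 6 largest and 6 smallest log2 fold changes and up to 3 members of each list by absolute log2 fold change. Fbxo32, Trim63, Slc39a14, Mt1 and Mt2 were always included, and so were the 4 genes with opposite directions that differed most. The first 5 were chosen as atrophy ligases and zinc genes that this study was already known for. Their choice was therefore not blind to its results. Some genes that this rule picks are not reported here. Any other gene named was chosen after its values were seen. Alternatives tried were q of 0.01 or less, 1 FPKM or more in a group, an absolute log2 fold change of 1 or more, matching by identifier, and the log2(FPKM + 1) scale. A list of 56 liver and plasma genes was written after the tables were examined and before it was tested. Genes with close copies can share reads, so values of Acot1, the globins, Serpina3n, Hamp2, the MHC genes and ribosomal protein genes are uncertain. The same holds for genes that overlap another, since strand use is not stated. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.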

Results

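The transcriptome of tibialis anterior muscle was compared between healthy mice and mice with cancer cachexia in 2 models. In the first, Balb/c mice carried 4T1, a metastatic mouse breast cancer line. In the second, CD2F1 mice carried C26m2, a metastatic mouse colon cancer line. Each of the 4 groups had 2 libraries, and healthy controls were of the same strain and age. Injection and surgery are recorded for the cachectic groups alone, so their effects cannot be told apart from those of cancer. Groups called tumour-bearing had metastases, their injected tumours having been cut out. The study asked how gene expression in muscle changes when metastatic cancer causes wasting. Values are the authors' group FPKM, 1 per group, so they are given with no spread between libraries, and folds are ratios of these values. Listed genes passed the authors' Cuffdiff test at q of 0.05 or less, with 2 libraries per group. Sequencing depth is unknown. Counts for a list are of its listed members, and most members of some lists were not listed.

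In muscle of 4T1-bearing mice, the ubiquitin ligases that mark muscle atrophy were among the most abundant genes that rose. Trim63 (MuRF1) rose from 91.6 to 2179.6 FPKM, a 23.8-fold change, and Fbxo32 (atrogin-1) rose 18.8-fold, from 47.8 to 901 FPKM. The zinc importer Slc39a14 rose 31.4-fold, and the metallothioneins Mt1 and Mt2, which bind zinc, rose 99.2-fold and 134-fold, to 2774 and 2138 FPKM. These ligases and zinc genes were named whatever their values. Neither the atrophy ligase list nor the zinc and iron list passed as a whole (Fisher's exact test, adjusted p = 0.254 and 0.864). Collagen, tendon and fast-fibre genes fell, Col1a1 from 105 to 1.01 FPKM and the kinase Mylk4 from 476 to 2.79 FPKM. In the authors' deposited table the q-value of each of these genes was 0.000382, which goes with the smallest p-value the test gave.

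The 4T1 table listed 4334 genes, 2303 higher and 2031 lower in tumour-bearing muscle. The median fold was 2.78 among the higher genes and 3.09 among the lower ones. Changes of 4-fold or more were seen in 651 higher and 712 lower genes. The 6 largest increases among genes at 1 FPKM or more were those of S100a8, S100a9, BC028471, Cxcr2, Cacna1i and Gm4876. S100a8 and S100a9, which encode the calprotectin subunits of neutrophils, rose from 0.666 to 1367 FPKM and from 0.860 to 615 FPKM. At q of 0.01 or less S100a8, BC028471, Cxcr2 and Gm4876 were no longer called, nor was Fam78a among the decreases. The 6 largest decreases were those of Ky, Kcng4, Mylk4, Fam78a, Gm15676 and Tmem233. Ky, a muscle gene whose loss causes kyphoscoliosis in mice, fell 309-fold, from 56.2 to 0.182 FPKM. Kcng4, a potassium channel subunit, fell 306-fold.

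Protein breakdown genes rose together in the 4T1 model. Of 41 proteasome genes, 25 were listed, 24 higher and 1 lower (Fisher's exact test, adjusted p = 6.78e-05). Psmd4 rose 5.43-fold, Psma7 4.31-fold and Psmd8 3.91-fold. Of 38 autophagy and lysosome genes, 18 were higher and 2 lower (Fisher's exact test, adjusted p = 0.00576). Among them the autophagosome gene Gabarapl1 rose 31.2-fold to 631 FPKM, the protease Ctsl 19.1-fold to 1260.5 FPKM and the mitophagy receptor Bnip3 7.51-fold. Targets of FoxO factors and glucocorticoids were higher in 24 of 27 listed members (Fisher's exact test, adjusted p = 0.000812), with Ddit4 up 37.5-fold, Irs2 26.8-fold and Cebpd 23.5-fold. The list of atrophy ubiquitin ligases, with 9 higher and 3 lower members, did not pass (Fisher's exact test, adjusted p = 0.254). ATF4 and endoplasmic reticulum stress genes were higher in 12 of 14 (Fisher's exact test, adjusted p = 0.0389). Ppp1r15a rose 15.1-fold and Atf3 11.3-fold, while the serine synthesis gene Psph fell 8.48-fold. The ATF4 result was lost at q of 0.01 or less, with 11 higher and 2 lower members, and without genes under 1 FPKM, with the same 12 and 2 (for both, Fisher's exact test, adjusted p = 0.0636).

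IL-6 and acute-phase genes and neutrophil markers rose in the 4T1 model. Of 15 listed members of the IL-6, STAT3 and acute-phase list, 14 were higher (Fisher's exact test, adjusted p = 0.00597). Lcn2 (lipocalin 2) rose from 1.17 to 125 FPKM, and the IL-6 receptor gene Il6ra rose from 0.849 to 41.0 FPKM. Neutrophil markers moved with this list: of 30, 8 were listed and all 8 were higher (Fisher's exact test, adjusted p = 0.0263). Their median fold was 90.8, and Lcn2 belongs to both lists. At q of 0.01 or less, with all 6 listed higher, the neutrophil list no longer passed (Fisher's exact test, adjusted p = 0.0757). The NF-kB and TNF list had 11 higher and 3 lower members (Fisher's exact test, adjusted p = 0.117), with Map3k14 up 4.91-fold and Il1b up from 0.120 to 1.42 FPKM. Il1b is also a neutrophil marker. Macrophage markers went both ways, 9 higher and 5 lower (Fisher's exact test, adjusted p = 0.589). Cd68 rose 19.6-fold, Itgam 15.5-fold and Lgals3 12.6-fold, while Mrc1 fell 5.89-fold and Folr2 4.87-fold. Genes of interferon response and antigen presentation were lower in all 14 listed cases (Fisher's exact test, adjusted p = 0.000257). H2-Ab1 fell 4.16-fold, Isg15 4.00-fold and Igtp 3.55-fold, of which Igtp alone stayed called at q of 0.01 or less.

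Matrix, fast-fibre, glycolysis and myogenesis genes fell in the 4T1 model. All 32 listed matrix genes were lower (Fisher's exact test, adjusted p = 1.64e-09), led by Col1a1, Col6a3 and Col1a2 with falls of 104.5-fold, 49.2-fold and 37.8-fold. Fibroblast markers moved with the matrix, with all 13 listed lower (Fisher's exact test, adjusted p = 0.000412), as did tendon markers, with all 6 lower (Fisher's exact test, adjusted p = 0.0294). Lum fell 18.6-fold, Thy1 10.9-fold and Fmod 98.0-fold. Of 28 fast-fibre genes, 10 were listed and 9 of these were lower (Fisher's exact test, adjusted p = 0.0257). Among them were Mylk4 and the calcium-storage protein gene Casq1, which fell from 1491 to 31.3 FPKM. Glycolysis and glycogen genes were lower in 14 of 18 (Fisher's exact test, adjusted p = 0.0265), with Gpd1 down 19.8-fold, Phka1 10.2-fold and Pgam2 from 1998 to 199 FPKM. At q of 0.01 or less this list did not pass (Fisher's exact test, adjusted p = 0.0663). Satellite-cell and myogenesis genes were lower in 12 of 13 (Fisher's exact test, adjusted p = 0.00576). Igfbp5 fell 15.8-fold and Mef2c 13.4-fold, while Myog, a myogenic factor, rose 9.98-fold.

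The remaining 4T1 lists did not pass Fisher's exact test after adjustment, apart from the epithelial list, which was not tested. Fatty acid genes were higher in 16 of 21, with Acot1 up 92.3-fold and the lipase Pnpla2 6.04-fold. This list passed at q of 0.01 or less (Fisher's exact test, adjusted p = 0.0200). Clock genes were higher in 9 of 10, with Cry2 up 16.8-fold and Nfil3 15.7-fold, and endothelial markers in 9 of 10, with Plvap up 4.22-fold and Kdr down 3.65-fold. Of 83 oxidative phosphorylation genes, 10 were listed and 8 of these were lower, with Ndufs1 down 2.80-fold. TCA cycle and biogenesis genes were lower in 7 of 10, but Ppargc1a (PGC-1alpha) rose 11.6-fold. Zinc and iron genes had 4 higher and 5 lower members, with the transferrin receptor Tfrc down from 119 to 2.54 FPKM. TGF-beta genes split 10 and 10, denervation genes 8 higher and 9 lower, slow-fibre genes 5 higher and 4 lower. Runx1, which rises in denervated muscle, rose 21.5-fold, Ache fell 13.2-fold, Sln (sarcolipin) rose 30.6-fold and Tgif1 14.8-fold. IGF and mTOR genes were higher in 17 of 27, and stress and heat shock genes in 11 of 14. Of 30 proliferation genes, 4 were listed and 1 of these was higher, while Aurka fell 10.7-fold. Globin and other red cell genes were higher in 5 of 7, with Hba-a1 up 5.67-fold. Of the listed genes on the lymphocyte list, Coro1a and Ptprc rose 8.17-fold and 8.13-fold, and Ighm fell 85.1-fold from 102 FPKM. Adipocyte markers split 2 and 2, both listed Schwann cell markers were lower, and the epithelial list had 1 listed member, Lgals4, which rose 4.00-fold. The smallest listed absolute log2 fold change was 0.72 in this table and 0.48 in the C26m2 table.

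**Figure D1:**
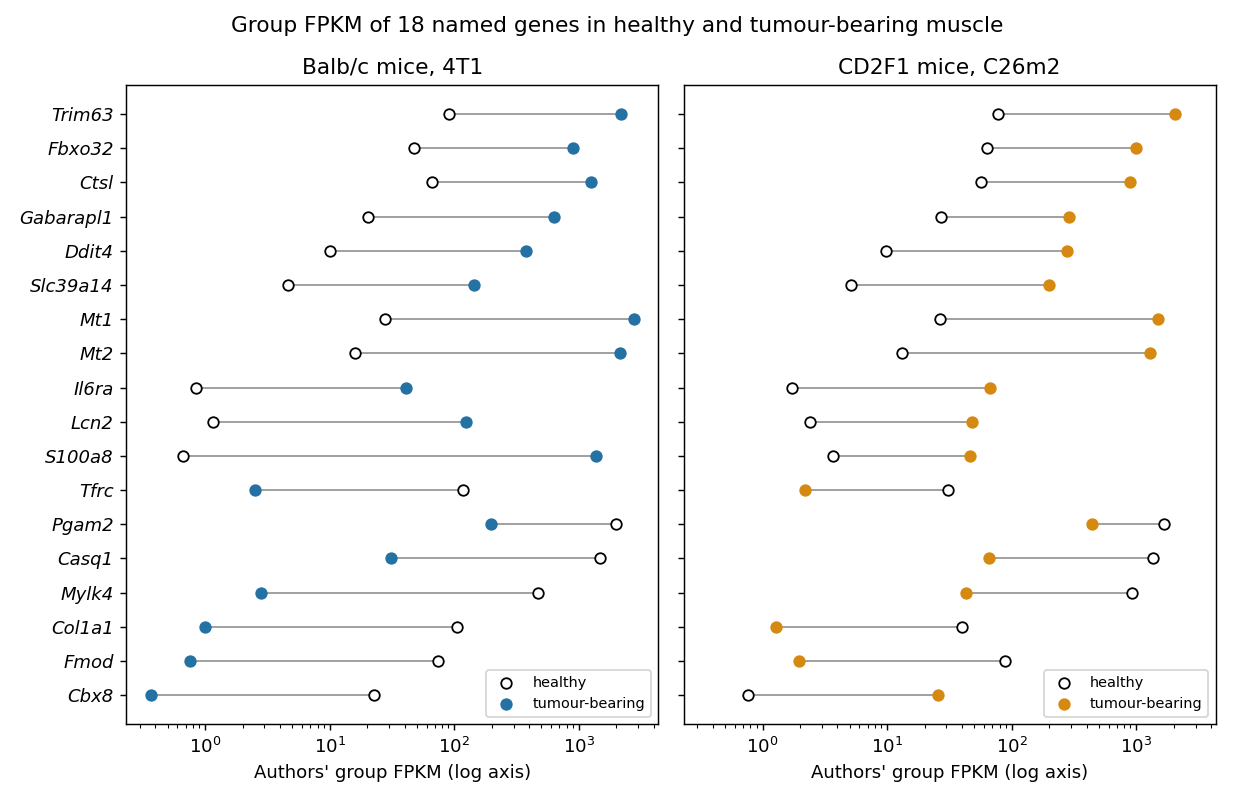
Authors' group FPKM (log axis) of 18 genes in healthy (open circles) and tumour-bearing muscle (filled circles), for 4T1 in Balb/c mice on the left and C26m2 in CD2F1 mice on the right; each circle is 1 group value. Trim63 rose from 91.6 to 2179.6 FPKM on the left and from 77.4 to 2053.8 FPKM on the right, whereas Cbx8 fell from 22.9 to 0.365 FPKM on the left and rose from 0.760 to 25.5 FPKM on the right.

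In muscle of C26m2-bearing mice, the same ligases and zinc genes were high. Trim63 rose 26.5-fold, from 77.4 to 2053.8 FPKM, and Fbxo32 rose 15.7-fold, from 64.0 to 1006 FPKM. Slc39a14 rose 38.4-fold, from 5.17 to 198 FPKM, Mt1 56.6-fold and Mt2 97.6-fold. As in 4T1, the atrophy ligase list and the zinc and iron list did not pass (Fisher's exact test, adjusted p = 0.148 and 0.887). Collagen and tendon genes fell here too, Col1a1 from 40.1 to 1.28 FPKM and Tnmd (tenomodulin) from 9.23 to 0.196 FPKM. In the authors' deposited table the q-value of each of these genes was 0.000319, again that of the smallest p-value.

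The C26m2 table listed 4832 genes, 2847 higher and 1985 lower. With a minimum absolute log2 fold change of 1, 3129 remained, 1707 of them higher. The median log2 fold change was 1.14 among higher and -1.38 among lower genes. The largest increases included those of Fam65c, Mt2, Doc2b, Acot1 and Armc2, with Fam65c up 197.5-fold, from 0.114 to 22.5 FPKM. The 6 largest decreases were those of Lrrc38, Ky, Pld5, Gdap1, Plcd4 and Dnm3os. Lrrc38, an auxiliary subunit of potassium channels, fell 147-fold, Ky 114-fold and the mitochondrial gene Gdap1 83.7-fold. Dnm3os, a noncoding RNA, fell 73.7-fold.

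Of 36 listed proteasome genes, 35 were higher in C26m2-bearing muscle (Fisher's exact test, adjusted p = 3.36e-06). Psma7 rose 5.24-fold, Psmd4 5.17-fold and Psmc4 5.00-fold. Autophagy and lysosome genes were higher in 21 of 24 (Fisher's exact test, adjusted p = 0.0117), with Ctsl up 15.8-fold and Gabarapl1 10.7-fold. FoxO and glucocorticoid targets were higher in 26 of 31 (Fisher's exact test, adjusted p = 0.0173). Cdkn1a (p21) rose 32.2-fold, Pnmt 31.3-fold and Ddit4 28.7-fold. Fatty acid genes were higher in 26 of 30 (Fisher's exact test, adjusted p = 0.00597). Pdk4, which inhibits pyruvate dehydrogenase, rose 20.3-fold to 1819.9 FPKM, and Acot1 rose 61.1-fold, while the desaturase gene Scd1 fell 9.54-fold.

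Matrix genes were lower in 28 of 32 in the C26m2 model (Fisher's exact test, adjusted p = 3.36e-06), with Col1a2 down 18.3-fold and Tnc (tenascin C) from 1.21 to 0.0806 FPKM. The basement membrane collagen genes Col4a1 and Col4a2, named after their values were seen, were among the 4 that rose, 2.08-fold and 2.46-fold. Fibroblast markers moved with the matrix, lower in 13 of 14 (Fisher's exact test, adjusted p = 0.000572), and tendon markers in all 7 (Fisher's exact test, adjusted p = 0.00785). Dpp4 fell 15.7-fold, Pi16 14.7-fold and Cilp2 57.6-fold. Fast-fibre genes were lower in 14 of 15 (Fisher's exact test, adjusted p = 0.000322), with Mylk4 down 21.6-fold and Casq1 20.4-fold. Glycolysis and glycogen genes were lower in 15 of 22 (Fisher's exact test, adjusted p = 0.0389), with Phka1 down 8.04-fold and Pgm2 5.50-fold, a result lost with a minimum absolute log2 fold change of 1 (Fisher's exact test, adjusted p = 0.0815). Interferon and MHC genes were lower in all 17 (Fisher's exact test, adjusted p = 4.15e-06), with Igtp down 8.31-fold and Ifit3 6.85-fold. Macrophage markers moved with them, lower in 12 of 14 (Fisher's exact test, adjusted p = 0.00597), with Ms4a7 down 11.3-fold, Folr2 8.16-fold and Mrc1 6.05-fold, Ms4a7 not being called at q of 0.01 or less, while Cd68 rose 3.98-fold and Lgals3 2.77-fold. All 12 listed endothelial markers were higher (Fisher's exact test, adjusted p = 0.00809), with Apold1 up 6.70-fold and Cldn5 5.08-fold. That result was lost at q of 0.01 or less, with 8 listed, and with a minimum absolute log2 fold change of 1, with 6 listed, all higher (Fisher's exact test, adjusted p = 0.0636 and 0.0800).

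The other C26m2 lists did not pass Fisher's exact test after adjustment, apart from the epithelial list, which was not tested. IL-6, STAT3 and acute-phase genes had 14 higher and 7 lower members (Fisher's exact test, adjusted p = 0.645). Il6ra rose 39.1-fold, Serpina3n 25.9-fold and Lcn2 20.1-fold, while the fibrinogen genes Fga, Fgb and Fgg fell 9.62-fold, 7.52-fold and 10.1-fold. Liver transcripts fell as well: of 38 listed genes from a list of 56 liver and plasma genes, 37 were lower, with albumin (Alb) going from 79.5 to 8.11 FPKM. This liver list shares 5 genes with the acute-phase list, so the falls are in part those of the same genes. Without liver-list genes the acute-phase list had 14 higher and 2 lower members. Zinc and iron genes had 9 higher and 5 lower members. Hamp2, a hepcidin gene, rose 50.8-fold to 492 FPKM, and the transferrin gene Trf, which is on the liver list, fell 8.44-fold. Atrophy ligases were higher in 11 of 13, with Ubb up 5.03-fold, ATF4 and stress genes in 13 of 16, with Ppp1r15a up 11.6-fold, and oxidative stress and heat shock genes in 15 of 18, with Gclm up 5.56-fold. The last list passed with a minimum absolute log2 fold change of 1 (Fisher's exact test, adjusted p = 0.0271). Clock genes were higher in 10 of 13, with Arntl (Bmal1) up 10.9-fold, IGF and mTOR genes in 19 of 28, with Eif4ebp1 up 12.8-fold, and NF-kB genes in 8 of 11, with Tnfrsf12a up 5.93-fold. TGF-beta genes had 14 higher and 10 lower members, with Inhbb up 22.3-fold. Slow-fibre genes were higher in 6 of 8 and denervation genes in 7 of 13. Oxidative phosphorylation and TCA cycle genes were each higher in 5 of 8 listed, from lists of 83 and 35. Myogenesis genes were lower in 7 of 12, with Myod1 down 5.55-fold, and proliferation genes in 5 of 6. All 6 neutrophil markers were higher (Fisher's exact test, adjusted p = 0.148), S100a8 going from 3.71 to 46.2 FPKM. Red cell genes were higher in 3 of 4, and adipocyte markers were lower in 7 of 9, Adipoq falling 13.2-fold. All 4 Schwann cell markers and the single listed lymphocyte marker, Ighm, were lower, and the epithelial list had 1 higher and 1 lower member.

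**Figure D2:**
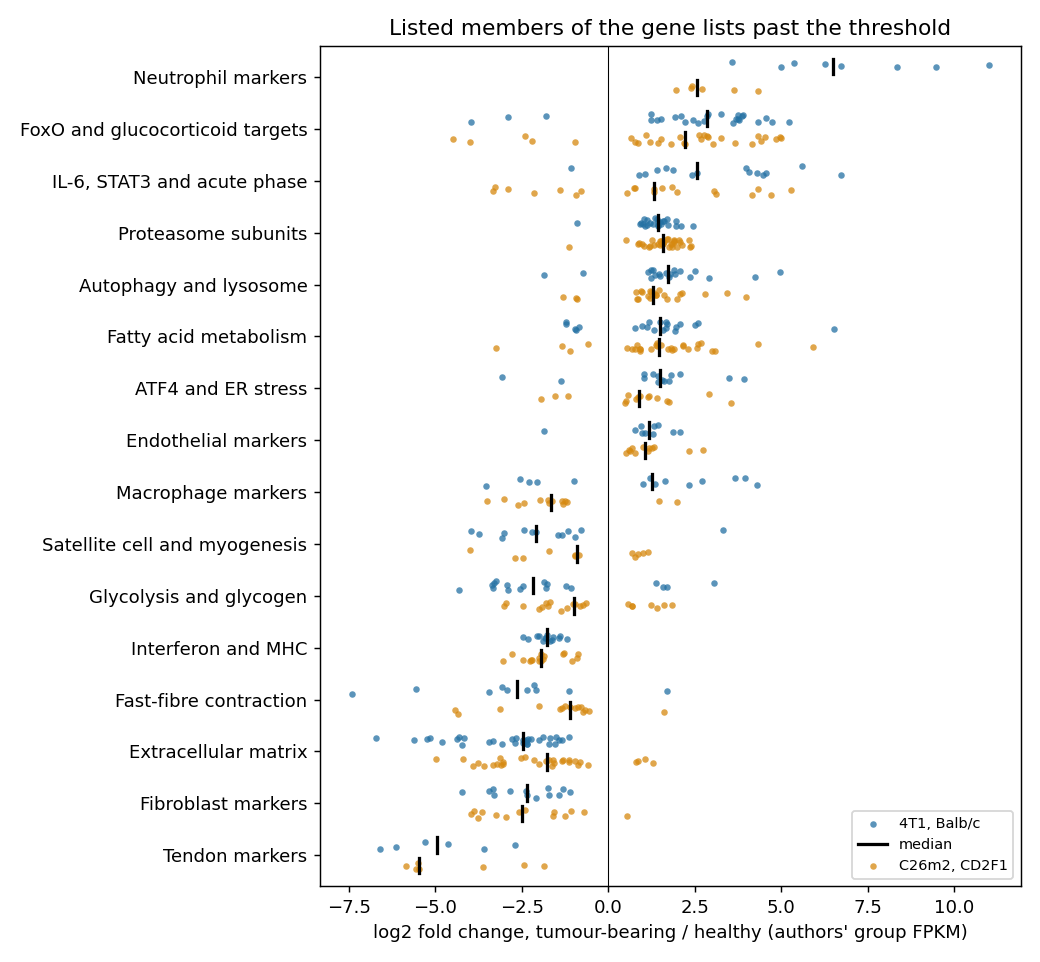
Log2 fold change, tumour-bearing over healthy from the authors' group FPKM, of each listed member (points) of the 16 lists that passed Fisher's exact test in at least 1 model, with the median as a bar; blue is 4T1 in Balb/c mice and orange is C26m2 in CD2F1 mice. All 32 listed matrix genes lie below 0 for 4T1 and 28 of 32 for C26m2, and all 8 neutrophil markers lie above 0 for 4T1.

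The models overlapped widely. Of the listed genes, 3134 were in both tables, and 3108 of them (99.2%) changed in the same direction, 1742 higher and 1366 lower. Independent lists of these sizes among 13121 tested genes would share 499.7 higher and 307 lower genes, and the log10 of the hypergeometric p-value was -877.5 and -828. The comparisons share no library, but genes are not independent replicates. Across genes listed in both, Pearson's r of the log2 fold changes was 0.93 and Spearman's rho 0.92. Listing leaves out genes with small changes, which may raise both values, so they do not describe all genes tested. Of the lists, 9 passed in both models: proteasome, autophagy, FoxO targets, matrix, fast fibre, glycolysis, interferon, fibroblast and tendon. The higher and lower members of each list in 4T1 were also set against those in C26m2. The split differed in none of 32 lists after adjustment (Fisher's exact test, smallest adjusted p = 0.586). Genes listed in both tables, such as 26 FoxO and glucocorticoid targets, were counted on both sides as if independent. The result therefore cannot be read as agreement between the models. The macrophage list alone had an unadjusted p under 0.05 (Fisher's exact test, p = 0.0183), though all 7 of its members listed in both tables moved in the same direction.

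Folds were larger in 4T1 in 71.8% of the 3108 genes, with median folds of 3.05 and 2.57. All 9 fast-fibre genes and all 15 glycolysis genes listed in both fell or rose by more in 4T1. Of 24 proteasome genes listed in both, 3 changed more in 4T1 and the others more in C26m2, and of 16 fatty acid genes 5 changed more in 4T1. Model and strain go together in this design, so these are differences of model with strain. Among the 1173 genes at the smallest p-value in both tables, 75.5% had the larger fold in 4T1. The smallest listed absolute log2 fold change was 0.72 in 4T1 and 0.48 in C26m2. Selection of genes by listing, or by the smallest p-value, may therefore favour larger folds in 4T1 in these counts. No gene of equal sign passed the test on single genes, which misses most such differences.

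The direction was opposite in 26 genes, 13 each way. They are also the 26 genes that passed the test of a difference between models, which adds nothing to their signs, since each was called in both tables. The 4 with the largest difference were Cbx8, Hp, Adamts8 and Katnal2. Cbx8, a Polycomb subunit, fell from 22.9 to 0.365 FPKM in Balb/c and rose from 0.760 to 25.5 FPKM in CD2F1 mice. Hp (haptoglobin) rose from 0.801 to 18.0 FPKM in 4T1 and fell from 7.79 to 2.98 FPKM in C26m2. Adamts8, a secreted protease, fell from 6.96 to 0.527 FPKM in 4T1 and rose from 0.948 to 2.74 FPKM in C26m2. Katnal2 rose from 0.230 to 0.906 FPKM in 4T1 and fell from 4.07 to 0.668 FPKM in C26m2.

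**Figure D3:**
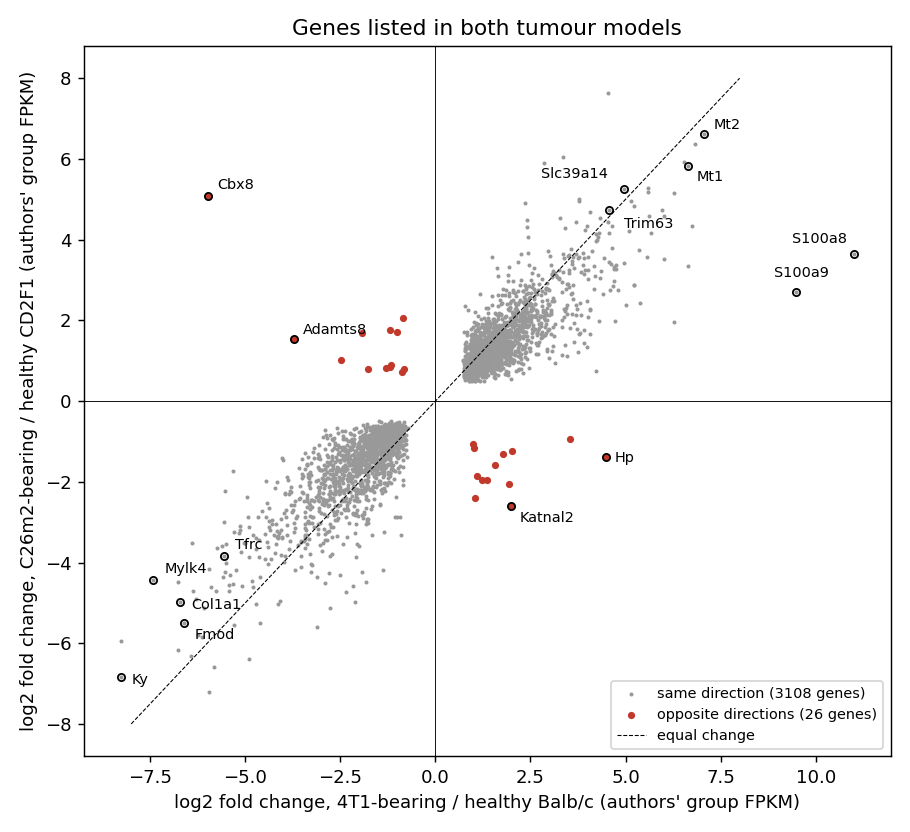
Log2 fold change in 4T1-bearing (horizontal axis) and in C26m2-bearing muscle (vertical axis) of the 3134 genes listed in both tables, from the authors' group FPKM; grey points changed in the same direction, red points in opposite directions and the dashed line marks equal change. The 26 red genes include Cbx8 and Hp, and S100a8 and S100a9 lie far to the right of the line.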

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

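The tests of the neutrophil and fibroblast patterns were chosen after their results were seen; the liver list was written after some of its genes had been seen and before it was tested.

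Between models, 26 genes were called in opposite directions, and the test of the difference passed these genes alone, which their signs already fix. The differences, 4T1 minus C26m2 on the log2 scale, were -11.04 for Cbx8, 5.87 for Hp, -5.25 for Adamts8 and 4.58 for Katnal2. Hp is also on the liver list weighed below, as are Serpina1b and Cyp2e1, which are among the 26 as well.

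Liver genes fell in C26m2-bearing muscle. Of 38 listed genes from the list of 56, 97.4% were lower, by a median of 7.15-fold, and Alb, Trf and Apoa1 led the healthy CD2F1 group with 79.5, 48.3 and 28.5 FPKM. Liver RNA in the healthy CD2F1 libraries, or in 1 of the 2, could leave such falls. Carry-over of this kind may account for the falling fibrinogen, C3 and Trf values. It may also account for part of the opposite directions of Hp, Serpina1b and Cyp2e1. The falls were not equal (Cochran's Q = 68.4 over the 37 lower genes), Vtn falling 1.58-fold and Alb 9.80-fold, and 13 of the 38 stood at 1 FPKM or more in tumour-bearing muscle as well. The same carry-over in healthy Balb/c libraries cannot be decided from the 5 liver genes in the 4T1 table, 20.0% of them lower. Unlisted genes, Alb among them, give no verdict. Hp, Serpina1b and Cyp2e1 stood at 0.801, 1.27 and 0.520 FPKM in healthy Balb/c muscle, against 7.79, 12.4 and 5.60 FPKM in healthy CD2F1 muscle. Fah and Vtn stood no lower in Balb/c. A change in the muscle itself, or a strain difference, stays open and was not tested.

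Neutrophil genes rose by a median of 90.8-fold in 4T1-bearing muscle and 5.91-fold in C26m2-bearing muscle. For the 8 listed markers, more blood of fixed composition is argued against. Their median lay 4.13 above the globin median on the log2 scale, and the lowest neutrophil value, 3.57, lay above the highest globin value, 2.50. Genes near 0 FPKM tend to be listed only with large folds, and 22 of the 30 neutrophil markers were not listed. The comparison therefore does not cover the unlisted markers. More neutrophils in the muscle or its blood stays open: that all 8 markers rose (Fisher's exact test, p = 0.00863) is the pattern itself, and at q of 0.01 or less all 6 listed were higher but the list did not pass (Fisher's exact test, adjusted p = 0.0757). A signal from 1 of the 2 tumour libraries cannot be told apart without values per library; 3 of 7 neutrophil genes with a log2 fold change of 5 or more were above the smallest p-value, against 28.7% of 80 other genes (Fisher's exact test, p = 0.422). Strain and model are confounded, so neither was tested as the source of the gap between models.

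Fibroblast genes fell in both models. The listed markers changed by unequal factors (Cochran's Q over the implied standard errors, the larger p of the models = 0.00569, in 4T1). All 13 fell in 4T1, while 1 of the 14 in C26m2 rose and was kept in the test. The inequality argues against 1 common fall of all listed markers. It cannot decide on a loss of fibroblasts alone, since markers also made by other cells would fall less. A larger share of fibre RNA that lowers all other cell types alike is argued against by endothelial markers, higher in 9 of 10 in 4T1 and in all 12 in C26m2. Their smaller median log2 fold change of the models was 1.08. Other cell types did fall: all listed tendon and Schwann cell markers were lower in both models. Macrophage markers were lower in 12 of 14 in C26m2 but higher in 9 of 14 in 4T1. The endothelial list did not pass in 4T1 (Fisher's exact test, adjusted p = 0.0564), and at q of 0.01 or less it did not pass in C26m2 with all 8 listed members higher (Fisher's exact test, adjusted p = 0.0636). Lower transcription of matrix genes within fibroblasts, with or without fewer of them, stays open and was not tested.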

How the results depend on the processing

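The alternatives that leave out liver-list genes, trim the acute-phase or matrix list, or put named genes on the log2(FPKM + 1) scale were chosen after seeing the data. With a minimum absolute log2 fold change of 1, the C26m2 table held 3129 genes, 1707 of them higher, against 4832 and 2847, because it lists smaller changes. At q of 0.01 or less in both tables, 2067 genes were shared, against 3134, by construction of the stricter limit, and 99.4% changed in the same direction. Counting genes that differ between models by 1 or more on the log2(FPKM + 1) scale, with no test, gave 275 in place of 26. Of these, 235 had the larger absolute log2 fold change in 4T1 by the deposited values, to which nothing was added. The selection of listed genes may favour this. All other counts of called, shared and differing genes stayed within 1.5 times, and the share with the same direction ran from 99.2% to 99.4% over all alternatives. The lists past the threshold numbered 11 to 14 in 4T1 and 11 to 12 in C26m2. Without liver-list genes the acute-phase list of C26m2 had 14 higher and 2 lower members (Fisher's exact test, adjusted p = 0.0517). The matrix list kept its side of the threshold in both models without the 3 genes it shares with fibroblast markers; it shares none with tendon markers. Of 211 named values, 15 were not called at q of 0.01 or less, and 62 moved by more than the implied standard error on the log2(FPKM + 1) scale, with none reversed. No paired analysis was possible because 1 value per group was used. Leaving out replicates, another pseudocount on library values and per-library fits were not run for the same reason, and unknown depth limits what can be said of genes near 0 FPKM.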

Other observations

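All tests in this part were chosen after the data were seen, on 12 gene families picked by symbol. Their p-values treat the genes of a family as independent.

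Cytosolic ribosomal protein genes, initiation factors, RNA helicases and ubiquitin-specific proteases rose in both models. All 52 listed cytosolic ribosomal protein genes were higher in 4T1-bearing muscle (Fisher's exact test, adjusted p = 1.04e-13), and so were all 49 listed in C26m2-bearing muscle (Fisher's exact test, adjusted p = 6.97e-11). Their median log2 fold changes were 1.06 and 0.69. These genes have many near-identical copies, which can share reads. Translation initiation factors (Eif) were higher in 22 of 25 in 4T1 (Fisher's exact test, adjusted p = 0.00115) and in 34 of 36 in C26m2 (Fisher's exact test, adjusted p = 1.47e-05). RNA helicases (Ddx and Dhx) were higher in 17 of 18 and in all 27 (Fisher's exact test, adjusted p = 0.000729 and 6.85e-06). Ubiquitin-specific proteases (Usp) were higher in 12 of 13 and in all 13 (Fisher's exact test, adjusted p = 0.00902 and 0.00289).

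Mitochondrial ribosomal protein genes (Mrpl and Mrps) were lower in 12 of 15 in 4T1 (Fisher's exact test, adjusted p = 0.0305) and split into 8 higher and 7 lower in C26m2 (Fisher's exact test, adjusted p = 0.898). Whether the models differ in this was not tested. Solute carriers, zinc finger proteins and potassium channels passed in neither model. RNA-binding motif (Rbm) and J-domain chaperone (Dnaj) genes were higher in 17 of 19 and 12 of 13 in C26m2 (Fisher's exact test, adjusted p = 0.0164 and 0.0342). In 4T1 they were higher in 11 of 14 and 9 of 13 (Fisher's exact test, adjusted p = 0.102 and 0.352), and a difference between models was not tested. Collagens, counted by symbol, were lower in all 18 in 4T1 and in 17 of 19 in C26m2 (Fisher's exact test, adjusted p = 6.85e-06 and 6.7e-05). Apolipoproteins, which the liver list also holds, were lower in 10 of 11 in C26m2 (Fisher's exact test, adjusted p = 0.00249). Fah, a liver-list enzyme of tyrosine breakdown, rose in both models, from 1.96 to 68.6 FPKM in 4T1 and from 1.91 to 59.3 FPKM in C26m2.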
